A study of Homo sapiens with 6 samples.

How the data were processed

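RNA was measured in 6 libraries labelled as HCT8, an established human colorectal cancer cell line. Per the labels, 3 libraries came from cells transfected with a control plasmid and 3 from cells transfected with a KDM4A overexpression plasmid, and all carry the same batch number. Per the labels' protocols, total RNA was extracted with Trizol and made into mRNA libraries for Illumina sequencing. The transfection time, the sequence of the plasmid insert and the strand setting are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

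The deposited table holds raw read counts per gene, 1 column per library, for 60664 genes with Ensembl identifiers, symbols, gene types, exon lengths and locations on GRCh38.p13, per the file headers. Per the submitters' processing notes, HISAT2, HTSeq and the GRCh38 build were used; the versions are not given in the sources used here. The counts are whole numbers with library totals that differ, and no normalization was applied to them before deposit as far as the values show. Reads that align to near-identical copies, such as metallothionein, ribosomal protein, histone, ZNF or CXCL genes, can be split or lost in such counting, and without a stated strand setting reads from overlapping antisense genes cannot be separated. Each column was matched to its sample by its name, and 0 columns of per-sample values were left unmatched.

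Library totals ranged from 14284240 to 23905980 counts. From the deposited counts, genes were kept by edgeR's filterByExpr (minimum count 10), which left 17147 genes holding 99.8% to 99.9% of each library's counts. TMM factors lay between 0.970 and 1.03. The main test was edgeR's quasi-likelihood test with robust estimation (glmQLFit, glmQLFTest) on the 2 groups without covariates, and adjusted p-values are Benjamini-Hochberg values over the 17147 genes, with a threshold of 0.05. Positive log2 fold changes mean higher in the KDM4A plasmid group. Levels are CPM (counts scaled by library total and TMM factor), as mean ± SD over 3 libraries, and SE is the standard error of the log2 fold change. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over that group, and with 1 to 3 counts it is a ratio with a 95% binomial interval. Such bounds and intervals cover counting error only.

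Gene lists were tested with camera at a preset inter-gene correlation of 0.01, for the 33 of 36 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over those lists. Each list's members that changed were also counted after adjustment over the list alone. Camera was repeated with an estimated correlation, and fry was run as an alternative. The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule took the KDM4 family, the 10 largest rises and falls and the 5 smallest p-values per direction among protein-coding genes that passed the test, averaged at least 1 CPM and had groups that did not overlap, and up to 4 members of each list (the 2 largest rises and the 2 largest falls among members that passed). Genes on chromosome Y and XIST were left out, and some names the rule took from lists that were not called are left out for length. Some genes the rule took are not reported here.

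The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions for the 17147 genes. Of 50 genes each changed by 1.5-fold, 2-fold, 4-fold and 8-fold, 70%, 80%, 94% and 96% were recovered, with 13 unchanged genes among 183 calls. The simulated changes were balanced up and down and far fewer than the 13480 genes called in the data. These rates therefore do not cover normalization when most genes change. Camera called a simulated list of 20 genes shifted 1.5-fold with either correlation, and 0 of 99 unchanged lists. Genes were drawn independently and lists at random, so the list check does not cover lists whose members vary together. Estimated correlations of the real lists reached 0.794. The chromosome window test called a simulated shifted window (permutation p = 0.00498, the smallest that 200 shuffles can give) and not data without 1 (permutation p = 0.204). The window shifted was the one highest in the real data, at 100 to 120 Mb of chromosome 13. Noise was independent between genes, so the window check does not cover neighbours that vary together for other reasons.

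Alternatives were a replicate block, DESeq2, limma-voom, edgeR's RLE factors, library size without a composition factor, no filter, a stricter filter (1 CPM and 10 counts in 3 libraries), library sizes without mitochondrial genes and KDM4A, estimation without the robust option, a test against 1.2-fold (glmTreat), and leaving out each library in turn. After the data were seen, a test against 2-fold and a fit with GC content and exon length trends removed from each library (as offsets) were added. GC content came from the longest GENCODE 29 transcript of each gene, matched by Ensembl identifier for 16987 tested genes (99.1%). Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.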

Results

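Gene expression was compared between libraries labelled as HCT8 colorectal cancer cells given a KDM4A overexpression plasmid and libraries labelled as HCT8 cells given a control plasmid, to find which genes and pathways change with KDM4A. KDM4A is a histone demethylase that acts on methylated lysines 9 and 36 of histone H3. The control libraries held 18380500, 19774634 and 22990881 counts, and the KDM4A plasmid libraries held 17737307, 23905980 and 14284240. Libraries of the same group correlated across genes at r = 0.993 to 0.995 (Pearson, log2 CPM), and libraries of different groups at 0.895 to 0.906. Counts of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 1.48 to 10.5, against 137 to 189 between groups). Each library was counted as 1 replicate, but such spread can be technical and does not show that the libraries came from separate cultures. The first principal component held 92.9% of the variance and separated the groups.

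KDM4A (ENSG00000066135, chromosome 1, 43650149 to 43705518, plus strand, GRCh38.p13) was higher in all 3 libraries given its plasmid. Its level was 44.7 ± 1.56 CPM in controls and 156 ± 3.90 CPM with the plasmid (SD, n = 3), a log2 fold change of 1.81 (SE 0.06, edgeR adjusted p = 7.2e-15). The single control libraries stood at 42.9, 45.9 and 45.3 CPM and the single KDM4A plasmid libraries at 152, 157 and 160 CPM. The counts do not separate plasmid mRNA from the cells' own. Rises of at least 2-fold were common (2814 genes), so this rise alone does not show that it came from the plasmid. Among related demethylases, KDM4D fell by 0.61 on the log2 scale (SE 0.13, adjusted p = 3.3e-04), and KDM4B had a log2 fold change of 0.01 (SE 0.07, adjusted p = 0.939). KDM4C rose by 0.18 (SE 0.07, adjusted p = 0.0322), a call that was lost in 9 of the other settings, with 5 of the 6 fits that left out a library among them. KDM4E had 0 counts in both groups. Of the 4 family members tested, 2 rose, 1 fell and 1 did not pass (3 adjusted over the list alone).

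**Figure D1:**
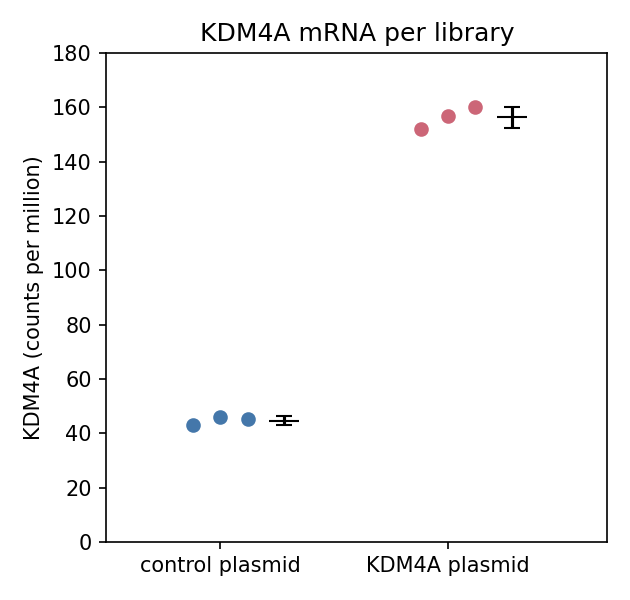
KDM4A level in CPM (vertical axis, from 0) in each library; coloured points are the 3 libraries of each group and black bars are the group mean ± SD. The control libraries lie at 42.9 to 45.9 CPM and the KDM4A plasmid libraries at 152 to 160 CPM.

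Most measured genes differed between the groups. Of 17147 genes tested, 6867 were higher and 6613 lower in the KDM4A plasmid group and 3667 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). By at least 2-fold, 2814 genes were higher and 2326 lower, and by at least 8-fold 808 were higher and 51 lower. In 79.7% of genes the 3 libraries of one group lay apart from the 3 of the other, where chance gives 10%. Beyond counting error, libraries of a group varied with a common coefficient of variation of 5.65%. Rises and falls were not mirror images. Of 1137 genes at 10 CPM or more in controls that were at least 2-fold lower by their mean CPM, 2 (ASNS and NTRK2) were more than 10-fold lower, whereas 256 of 1291 genes at 10 CPM or more with the KDM4A plasmid and at least 2-fold higher were more than 10-fold higher. These limits were set after the data were seen, and among genes under 10 CPM in controls, 30 of 1213 that were at least 2-fold lower were more than 10-fold lower. NTRK2 was named after its values were seen and did not pass the test (adjusted p = 0.0951), and its control mean rests on 1 library (500 CPM in control replicate 2, against 15.5 and 5.79 CPM in the other controls).

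By fitted log2 fold change, the 10 largest rises included 2 metallothionein genes, 2 chemokine genes and the tight junction gene CLDN2. The metallothioneins MT1A (chromosome 16, 56638666 to 56640087) and MT1G had 0 counts in all control libraries and were at least 131-fold and 52.2-fold higher. CSF2, the gene of the cytokine GM-CSF, also had 0 control counts and was at least 52.6-fold higher. At their bounds, MT1G and CSF2 would lie below CXCL2 (CPM ratio 96.7), so their place among the 10 largest is not established. S100A9, a calcium-binding protein of inflammation, had 1 count in the controls and a ratio of 177 (95% counting interval 31.3 to 7034). The tight junction gene CLDN2 (chromosome X, 106900164 to 106930861) went from 0.454 ± 0.0790 to 72.4 ± 3.07 CPM (log2 fold change 7.30, SE 0.12, adjusted p = 1.7e-18). CCL5 (7.08, SE 0.21) and CCL2 (6.73, SE 0.30), both chemokines, the scavenger receptor OLR1 (7.02, SE 0.17), IGFL2 (6.91, SE 0.18) and the hexokinase-domain gene HKDC1 (6.67, SE 0.22) completed the 10 largest. The smallest p-values among rises belonged to S100A4 (7.42 ± 0.482 to 300 ± 9.34 CPM), the EGF receptor ligand EREG (16.0 ± 0.185 to 349 ± 5.55 CPM), the chemokine CXCL5 (61.5 ± 1.57 to 1730 ± 40.5 CPM), NQO1 (56.3 ± 1.47 to 1351 ± 45.9 CPM) and AKR1B10 (17.7 ± 1.45 to 551 ± 26.6 CPM), with adjusted p from 6.6e-19 to 7.9e-19.

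The largest falls were smaller in size. The zinc finger gene ZSCAN23 (chromosome 6, 28431930 to 28443502) fell by 4.23 on the log2 scale (SE 0.31), and the log2 fold change was -3.63 (SE 0.19) for RAB39A and -3.35 (SE 0.16) for ASNS, which makes asparagine. Log2 fold changes of PTGFR, the prostaglandin F receptor (-3.32), the mitochondrial folate enzyme gene ALDH1L2 (-3.23), CSRNP3 (-3.23), the arrestin-domain gene ARRDC4 (-3.18), TENM1 (-3.13), the mTOR inhibitor gene DDIT4 (-3.03) and NCR3LG1 (-2.94), a ligand of an NK cell receptor, completed the 10 largest. The smallest p-values among falls belonged to ARRDC4 (261 ± 11.5 to 28.9 ± 1.19 CPM, adjusted p = 1.2e-17), DDIT4 (200 ± 6.75 to 24.4 ± 2.48 CPM), TSC22D3 (730 ± 29.9 to 124 ± 5.49 CPM), ALDH1L2 (178 ± 13.2 to 19.0 ± 1.86 CPM) and the branched-chain aminotransferase gene BCAT1 (271 ± 4.54 to 60.8 ± 1.01 CPM).

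**Figure D2:**
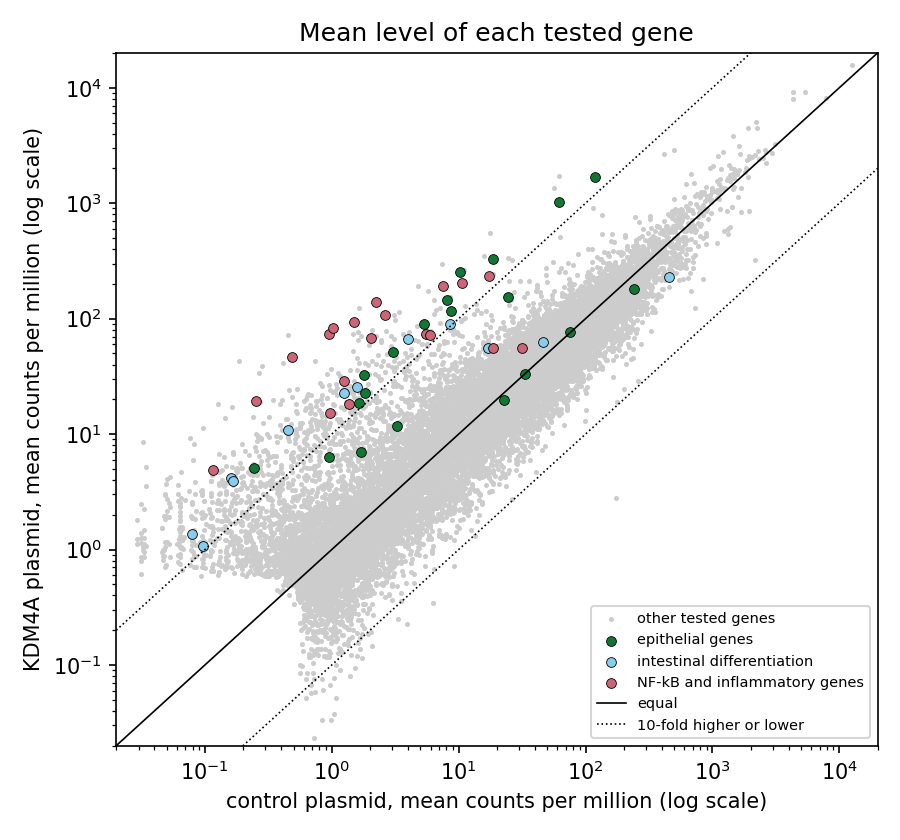
Mean CPM of each tested gene with the control plasmid (horizontal, log scale) and the KDM4A plasmid (vertical, log scale); each point is a gene averaged over 3 libraries per group, coloured for 3 gene lists. The 15 genes without counts in the control libraries are not drawn. Many coloured points lie above the upper dotted line of a 10-fold rise, and few genes at 10 CPM or more in controls lie below the lower line.

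Epithelial and intestinal genes were mostly far higher in the KDM4A plasmid group. Of 20 epithelial genes tested, 16 rose, 2 fell and 2 did not pass (18 changed adjusted over the list alone), with a median log2 fold change of 3.69 (camera adjusted p = 2.9e-28, and adjusted p = 0.0493 with an estimated correlation). The simple-epithelium keratin KRT19 went from 10.2 ± 0.804 to 254 ± 14.02 CPM and the claudin CLDN3 from 0.244 ± 0.0226 to 5.11 ± 0.935 CPM. Other members, named after their values were seen, were also low in the control libraries, with EPCAM at 18.7 ± 0.992 and 331 ± 17.8 CPM, KRT8 at 120 ± 4.43 and 1671 ± 90.2 CPM and KRT18 at 61.7 ± 3.07 and 1015 ± 43.9 CPM in the control and KDM4A plasmid groups. The desmosome gene DSP (-0.40) and the tight junction gene OCLN (-0.19) fell, but OCLN's call was lost in 5 settings, and neither was lower once GC and length trends were removed. Of 12 intestinal differentiation genes tested, 11 rose and 1 fell (12 adjusted over the list alone), with a median of 3.99 (camera adjusted p = 1.4e-08, and adjusted p = 0.0360 with an estimated correlation). The other 10 of the 22 genes on the list had too few counts to be tested in either group, among them KRT20 (7 and 11 counts over the 3 libraries of the control and KDM4A plasmid groups) and TFF3 (1 and 1), both named after their values were seen. Those that rose included the alkaline phosphatase gene ALPI (log2 fold change 4.62, SE 0.27) and the intestinal transcription factor CDX1 (4.57, SE 0.29), and the gene that fell was the carbonic anhydrase CA2 (458 ± 26.5 to 230 ± 4.98 CPM). IRS4, which is on no fixed list and was named after its values were seen, went the other way, from 2151 ± 202 to 323 ± 7.90 CPM (log2 fold change -2.74, SE 0.07, adjusted p = 1.0e-15). That the libraries of either group hold HCT8 cells rests on the labels alone. The low levels of epithelial genes and high level of IRS4 in the control libraries bear on every fold given here.

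Inflammatory and growth-signal genes rose together. All 20 tested NF-kB and inflammatory genes rose (20 adjusted over the list alone), with a median of 4.86, which was the same with CSF2 at its bound (camera adjusted p = 1.4e-53, and adjusted p = 0.0204 with an estimated correlation). IL6 and IL1B, also on the list and named after their values were seen, had too few counts to be tested. Over the libraries of the control and KDM4A plasmid groups, IL6 had 2 and 4 counts and IL1B 2 and 16. The neutrophil chemokine gene CXCL2 went from 0.484 ± 0.208 to 46.8 ± 2.13 CPM. Of 22 immediate early and MAPK feedback genes, 20 rose and 2 fell (22 adjusted over the list alone), with a median of 2.88 (camera adjusted p = 7.6e-17, but adjusted p = 0.0680 with an estimated correlation). The MAPK phosphatase gene DUSP6 (4.72, SE 0.09) and the AP-1 gene FOSL1 (4.67, SE 0.14) rose most, and JUN (-0.81, SE 0.06) and MYC (-0.75, SE 0.05) fell. Of 22 interferon response genes, 17 rose, 3 fell and 2 did not pass (20 adjusted over the list alone), with a median of 1.83 (camera adjusted p = 5.6e-05, but adjusted p = 0.154 with an estimated correlation). IRF7 rose by 5.26 (SE 0.44) and OAS1 by 4.21 (SE 0.19), while IFI44L (-0.77, SE 0.17) and DDX58 (-0.98, SE 0.34) fell. The falls of IFI44L and DDX58 were no longer called once GC and length trends were removed, and that of DDX58 was also lost with DESeq2 and without control replicate 1.

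Developmental pathway targets were higher as groups, each with members that fell. Of 22 Wnt/beta-catenin targets, 17 rose, 2 fell and 3 did not pass (19 adjusted over the list alone), with a median of 2.23 (camera adjusted p = 1.4e-11, and adjusted p = 0.0493 with an estimated correlation). The Wnt inhibitor gene APCDD1 (4.36, SE 0.11) and the stem cell factor ASCL2 (4.35, SE 0.34) rose most, and the transcription factor PROX1 fell by 2.07 (SE 0.14). Of 17 TGF-beta targets, 10 rose, 3 fell and 4 did not pass (13 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 7.2e-05, but adjusted p = 0.0691 with an estimated correlation). Of 24 YAP/TEAD targets, 18 rose, 5 fell and 1 did not pass (23 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 1.9e-05, but adjusted p = 0.0691 with an estimated correlation). CCN2, a matrix protein gene on both lists, went from 3.12 ± 0.326 to 108 ± 2.98 CPM, TGFBI rose by 4.87 (SE 0.24) and the kinase gene NUAK2 by 4.32 (SE 0.13). BHLHE40 (-1.51, SE 0.06), AMOTL1 (-1.58, SE 0.07) and DLC1 (-1.09, SE 0.07) fell.

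Stress-response lists were higher, each with members that fell. Of 20 genes on the NRF2 and ferroptosis defence list, 17 rose and 3 fell (20 adjusted over the list alone). Their median was 1.37 (camera adjusted p = 2.0e-17, and adjusted p = 0.0346 with an estimated correlation). Since the list also holds genes that promote ferroptosis, these counts give no direction of ferroptosis defence. The glutathione peroxidase gene GPX2 rose by 5.06 (SE 0.08) and AKR1B10 by 4.96 (SE 0.07), whereas the cystine transporter gene SLC7A11 (-1.47, SE 0.07) and ACSL4 (-0.90, SE 0.06), an enzyme that promotes ferroptosis, fell. Of 22 p53 targets, 15 rose and 7 fell (22 adjusted over the list alone), led by GDF15 (3.87, SE 0.11) and PHLDA3 (3.35, SE 0.12), with a median of 0.64 (camera adjusted p = 0.00241, but adjusted p = 0.184 with an estimated correlation). Of 12 heat shock genes, 9 rose and 3 fell (12 adjusted over the list alone), with HSPB1 rising by 2.40 (SE 0.06) and HSPA1A lower (-0.74, SE 0.11), and a median of 0.66 (camera adjusted p = 0.0297, but 0.0555 with limma-voom, and adjusted p = 0.401 with an estimated correlation). Of 20 autophagy and lysosome genes, 11 rose, 4 fell and 5 did not pass (15 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00652, but adjusted p = 0.184 with an estimated correlation, and 0.0743 with GC and length trends removed). SQSTM1, an autophagy receptor gene, went from 114 ± 1.67 to 907 ± 25.1 CPM and LAMP1 from 63.8 ± 1.76 to 272 ± 4.54 CPM.

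The ATF4 and amino acid response was lower. Of its 20 genes, 14 fell, 3 rose and 3 did not pass (17 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 2.0e-04, but adjusted p = 0.0691 with an estimated correlation). ASNS went from 13.5 ± 1.30 to 1.30 ± 0.318 CPM and DDIT4 fell by 3.03 (SE 0.07), while the transcription factor CEBPB rose by 1.38 (SE 0.09) and the pseudokinase TRIB3 by 0.50 (SE 0.07). TRIB3 had the opposite sign (-0.29) once GC and length trends were removed.

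DNA repair and ZNF genes were also lower as lists. Of 22 DNA repair genes, 17 fell, 4 rose and 1 did not pass (21 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00745, but adjusted p = 0.175 with an estimated correlation, and 0.195 with GC and length trends removed). XRCC2 (-2.35, SE 0.06) and ATM (-1.49, SE 0.08) fell, whereas RAD51C rose by 0.79 (SE 0.07). Of 406 ZNF genes, 217 fell, 106 rose and 83 did not pass (323 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00180, but adjusted p = 0.123 with an estimated correlation, and 0.0743 with GC and length trends removed). ZNF573 (-2.65, SE 0.21) and ZNF382 (-2.34, SE 0.13) fell most, and ZNF311 (4.47, SE 0.40) and ZNF544 (4.15, SE 0.18) rose most.

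Energy and translation genes rose as lists. All 22 oxidative phosphorylation genes rose (22 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.00136, but adjusted p = 0.420 with an estimated correlation, and 0.0628 with GC and length trends removed). The ATP synthase gene ATP5MC1 rose by 0.97 (SE 0.05) and the complex III gene UQCRQ by 0.94 (SE 0.06). Of 13 mitochondrially encoded genes, 9 rose, 1 fell and 3 did not pass (10 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.00745, but adjusted p = 0.572 with an estimated correlation). MT-ND1 went from 1462 ± 161 to 3858 ± 212 CPM and MT-ND2 from 1919 ± 196 to 4521 ± 393 CPM, and MT-ND4L fell by 0.24 (SE 0.07). Mitochondrial genes took 3.96% ± 0.252 of the counts in controls and 6.50% ± 0.341 with the KDM4A plasmid (SD, n = 3). Ribosomal protein genes took 6.67% ± 0.385 and 8.25% ± 0.0163, and lncRNA genes 2.97% ± 0.369 and 1.38% ± 0.0137. Of 79 cytosolic ribosomal protein genes, 68 rose, 2 fell and 9 did not pass (71 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 1.9e-04, but adjusted p = 0.605 with an estimated correlation, and 0.235 with GC and length trends removed). RPS26 and RPS27L each rose by 1.46 (SE 0.07), RPL36A fell by 0.40 (SE 0.07), and the fall of RPL39L (-0.29, SE 0.12) was lost in 5 settings.

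**Figure D3:**
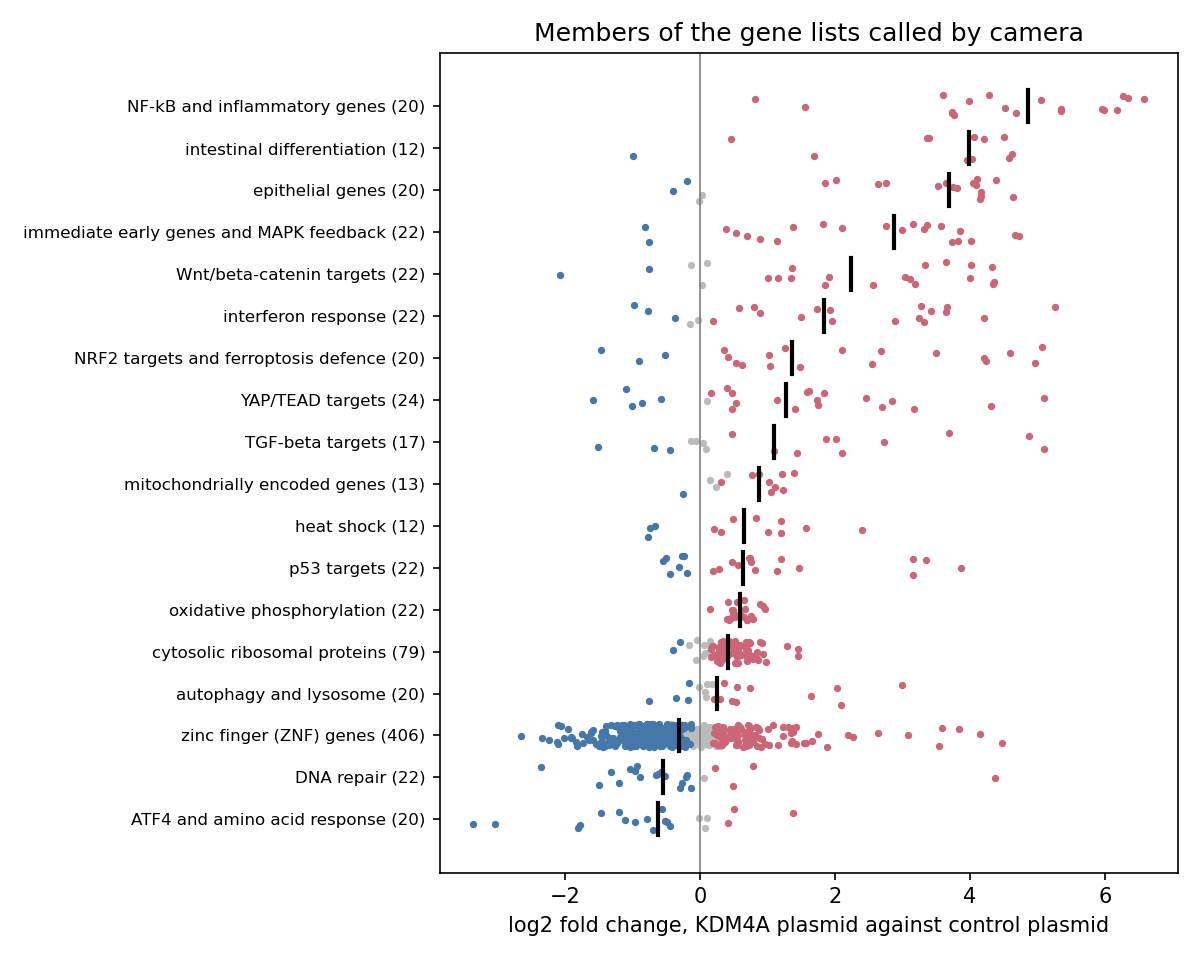
Log2 fold change (horizontal axis) of each member of the 18 gene lists called by camera at the preset correlation, with the number of tested members in brackets; red points rose, blue points fell, grey points did not pass, black bars are medians, and CSF2 is not drawn. The NF-kB list has the highest median (4.86) and the ATF4 list the lowest (-0.63).

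In all, camera called 18 of the 33 lists, 15 higher and 3 lower. The calls of 5 (NF-kB, NRF2, intestinal differentiation, Wnt and epithelial genes) held with an estimated correlation and the other 13 were lost.

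The enzymes and readers of the histone marks that KDM4A acts on were not called as a list (camera adjusted p = 0.0620). Of those 22 genes, 12 fell, 6 rose and 4 did not pass (18 adjusted over the list alone). The remodeller gene ATRX (-1.53, SE 0.06) and the methyltransferase gene ASH1L (-1.08, SE 0.07) fell, and the corepressor TRIM28 (0.91, SE 0.07) and the methyltransferase gene EHMT2 (0.76, SE 0.07) rose. Proliferation lists were not called either. S phase genes had 8 rises, 9 falls and 5 not passing of 22 tested (17 adjusted over the list alone, camera adjusted p = 0.819), with TYMS rising by 1.16 (SE 0.06) and MCM4 lower (-0.62, SE 0.05). G2/M genes had 6 rises, 13 falls and 2 not passing of 21 tested (19 adjusted over the list alone, camera adjusted p = 0.143), with CENPE lower (-1.37, SE 0.06). MYC targets had 10 rises, 7 falls and 5 not passing of 22 tested (17 adjusted over the list alone, camera adjusted p = 0.827), with POLR1B lower (-0.93, SE 0.05).

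Metabolic and remaining stress lists were also not called by camera. Hypoxia and glycolysis genes had 7 rises, 9 falls and 5 not passing of 21 tested (16 adjusted over the list alone, camera adjusted p = 0.895), among them the glucose transporter gene SLC2A1 (2.14, SE 0.06) and the kinase gene PDK1 (-1.79, SE 0.06). Cholesterol synthesis genes had 8 rises, 8 falls and 4 not passing of 20 tested (16 adjusted over the list alone, camera adjusted p = 0.895), with INSIG1 lower (-1.35, SE 0.06). Fatty acid synthesis genes had 3 rises and 8 falls of 11 tested (11 adjusted over the list alone, camera adjusted p = 0.599). Unfolded protein response genes had 11 rises, 4 falls and 1 not passing of 16 tested (15 adjusted over the list alone, camera adjusted p = 0.243). Apoptosis regulators had 13 rises, 6 falls and 2 not passing of 21 tested (19 adjusted over the list alone, camera adjusted p = 0.143), with BIK rising by 5.09 (SE 0.15) and BCL2L1 by 2.57 (SE 0.07). Camera's direction differed in sign from the mean in 3 lists (MYC, hypoxia, cholesterol) and from the median in 2 (MYC, cholesterol).

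Apart from endothelial markers, the remaining lists held both genes that rose and genes that fell. Mesenchymal genes had 10 rises, 10 falls and 1 not passing of 21 tested (20 adjusted over the list alone, camera adjusted p = 0.958). The matrix gene THBS1 rose by 4.35 (SE 0.08) and SNAI1 by 2.76 (SE 0.20), and LOX (-1.75, SE 0.10) and ZEB1 (-1.71, SE 0.08) fell. Notch pathway genes (receptors and ligands as well as targets) had 9 rises, 3 falls and 3 not passing of 15 tested (12 adjusted over the list alone, camera adjusted p = 0.305). The ligand gene JAG1 rose by 2.99 (SE 0.07). Colon stem cell genes had 7 rises, 5 falls and 1 not passing of 13 tested (12 adjusted over the list alone, camera adjusted p = 0.0695, and 0.0486 with GC and length trends removed). Replication-dependent histone genes had 17 rises, 2 falls and 6 not passing of 25 tested (19 adjusted over the list alone, camera adjusted p = 0.241). Fibroblast markers had 2 rises, 3 falls and 2 not passing of 7 tested (5 adjusted over the list alone, camera adjusted p = 0.359), with FBN1 at 39.3 ± 2.09 and 14.1 ± 1.17 CPM. Leukocyte markers had 3 rises, 1 fall and 1 not passing of 5 tested (4 adjusted over the list alone, camera adjusted p = 0.622), with group means from 0.0645 CPM (ITGAM in controls) to 2.32 CPM (CD14 with the KDM4A plasmid, named after its values were seen). Endothelial markers (3 tested, 2 rose, 1 did not pass, 2 adjusted over the list alone) and hepatocyte, neuronal and melanocyte markers (4 tested, 2 rose, 1 fell, 1 did not pass, 3 adjusted over the list alone) had too few members for the list test. Of the endothelial markers that rose, EGFL7 had the opposite sign with GC and length trends removed.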

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

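The test with GC and length trends removed and the test against 2-fold were chosen after the data were seen, and the other alternatives were planned. KDM4A kept its direction and call in every setting that tested it, with a log2 fold change of 1.76 to 1.83 when each library was left out in turn. Leaving out each library gave 6615 to 6969 genes higher, 6344 to 6795 lower, 5268 to 5533 changed at least 2-fold (main 5140, with fewer genes tested) and 18 to 19 lists called. Counts of higher and lower genes stayed within 1.5 times the main counts in the settings that test for any change, from 12629 calls with the stricter filter to 15055 without a filter. No main call was reversed outside the GC and length setting. A test against 1.2-fold (glmTreat) called 10982, against 5140 genes changed by at least 2-fold in the main test, since it sets a lower fold, and a test against 2-fold called 3654. Camera with an estimated correlation (median 0.0509, highest 0.794, against the preset 0.01) called 5 lists, and fry's directional test, which does not compare a list with other genes, called 29, against 18. With the replicate number as a block, 13242 genes were called, 13163 of them also called without it. The block took the calls of KDM4C and OCLN among the named genes. The numbers are a hint from the data at most, since deviations of same-numbered libraries correlated at -0.15, 0.03 and -0.09 and 1 of 3 control libraries matched its own number best. Removing GC and length trends moved the median of all genes from 0.03 to -0.12 and the share of calls that were higher from 50.9% to 42.6%. Of 13389 calls in that setting, 11310 were also called in the main test, 1270 of these in the opposite direction. Among named genes it turned the sign of BOP1 (-0.24), TRIB3 (-0.29), EGFL7 (-0.39), OCLN (0.41), DSP (0.00934), HSPA4L (0.10) and ATG12 (0.054), through the trend it takes out. Among all alternatives for the 154 named genes, 2417 values kept direction and call, 32 kept direction without the call and 7 turned. For the 18 called lists 287 kept both and 19 lost the call. Depth limits genes at a few counts, such as MT1A, MT1G, CSF2 and S100A9, to bounds or wide intervals.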

Other observations

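The tests in this part were chosen after the results they concern had been seen, other than the counts over other splits of the libraries. The gene families in this and the next paragraph were also picked after their values were seen. Members of several surface and secreted protein families rose with the KDM4A plasmid (edgeR, adjusted over all genes), and families picked in this way give no test of the family as a whole. All 6 tested ligands of the EGF receptor rose, among them AREG (6.60 ± 0.605 to 120 ± 5.16 CPM), BTC (log2 fold change 5.21, SE 0.27) and TGFA (2.34, SE 0.10). All 5 tested kallikrein-related peptidases, secreted serine proteases, rose, with KLK6 at 1.60 ± 0.283 and 76.1 ± 0.402 CPM and KLK10 at 1.69 ± 0.174 and 70.1 ± 1.44 CPM. Of 9 claudins, 7 rose and 2 fell, and CLDN3, CLDN4, CLDN6, CLDN7 and CLDN23 rose by 4.38, 4.10, 4.09, 4.09 and 4.07 on the log2 scale. CLDN15 (-0.49) and CLDN12 (-0.23) fell.

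All 5 tested metallothioneins rose, with a median log2 fold change of 5.71 when MT1A and MT1G are set to their bounds, and MT2A went from 2.98 ± 0.259 to 37.8 ± 5.12 CPM. Of 12 S100 genes 10 rose and 2 did not pass (S100A1 and S100A13), and S100A6 went from 4.80 ± 0.470 to 190 ± 7.01 CPM. Of 4 clustered protocadherin genes 1 rose (PCDHGA10) and 3 did not pass.

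Single libraries stood apart for 3 genes, by more than 4-fold from both others of their group. NTRK2, a neurotrophin receptor gene, was at 500 CPM in control replicate 2 and at 15.5 and 5.79 CPM in control replicates 1 and 3, against 2.54 to 3.25 CPM with the KDM4A plasmid. FGFR3 was at 40.5 CPM in control replicate 2 and at 260 and 187 CPM in the other controls, against 50.05 to 58.4 CPM with the KDM4A plasmid. NPIPA9, a member of a family of near-identical genes, was at 5.12 CPM in KDM4A plasmid replicate 1 and at 0.127 and 0.565 CPM in the others.

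The 26 epithelial and intestinal genes that rose at least 2-fold had a median rise of 4.03 (log2), and of 3.34 with GC and length trends removed. These genes were picked for rising in the same data, so their median alone decides little. Over all tested members of the lists fixed beforehand, the median went from 3.69 to 3.05 for epithelial genes and from 3.99 to 3.45 for intestinal genes. A smooth trend by GC content or gene length is therefore argued against as the whole cause. Different shares of 2 cell populations in the groups may be a candidate explanation, since medians over 146 windows of 20 Mb varied by chromosome block after GC and length trends were removed (SD 0.207, against at most 0.130 in 1000 shuffles of the genes, permutation p = 0.001, the smallest they can give), with the window at 100 to 120 Mb of chromosome 13 highest (39 genes, median 1.17). Such blocks could also appear if each group were a single, different population, so the window test does not single out different shares. A limit on falls at 1 ratio of shares was seen before it was considered. It largely held for genes at 10 CPM or more in controls (0.176% of 2-fold falls beyond 10-fold, against 19.8% of rises). It did not hold for ZSCAN23 (6.30 ± 1.84 to 0.341 ± 0.136 CPM) or RAB39A (9.13 ± 1.26 to 0.725 ± 0.188 CPM). Of 19 NF-kB genes at least 2-fold higher (CSF2 at its bound), 11 rose beyond 4.63, the highest value among these 26 genes. That value is only the highest of genes picked for rising, not a known ratio of shares. CLDN2, not among the 26, also rose beyond it (7.30). The larger NF-kB rises therefore do not decide for or against different shares. An identity check on genes whose levels are not given, with minimums set after the data were seen, found, in 6 of 6 libraries at a minimum of 5 counts and 5 of 6 at 10, a combination not usual for 1 cell line. Control RNA carried over into the KDM4A plasmid libraries, slow decay of mRNA after a short transfection, neighbours regulated together, and an effect of KDM4A itself, which is confounded with the groups, were not tested and stay open.

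IRS4 stood at 2151 ± 202 CPM in controls and is known for high expression in HEK293, a human embryonic kidney line, so cells of that type in the control libraries are a candidate source of signal, as a hypothesis. A list of 17 genes typical of that line was written from general knowledge after IRS4 had been seen, and of the 14 tested besides IRS4, 10 fell, 3 rose (PAX8, NES, FOXD1) and 1 did not pass, with a median of -0.61. The two-sided exact sign test gave p = 0.180. It takes genes, which are not independent replicates, by their sign alone, so it leaves the question open. The most abundant members were LIN28B (217 ± 5.41 to 59.8 ± 1.85 CPM), NEFM (209 ± 13.8 to 73.5 ± 4.96 CPM), HMGA2 (123 ± 5.16 to 65.5 ± 2.09 CPM) and NEFL (112 ± 5.06 to 45.8 ± 1.85 CPM), all 14 were also counted in the KDM4A plasmid libraries, and 1 (SOX2) is on the colon stem cell list.

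Short, GC-rich genes tended to be higher and long, AT-rich genes lower with the KDM4A plasmid, and the share of lncRNA counts was also lower, at 1.38% ± 0.0137 against 2.97% ± 0.369 (SD, n = 3). Across genes, which are not independent replicates, log2 fold change correlated with GC content at Spearman 0.391 and with exon length at -0.303, and both explained 14.1% of its variance; deviations of single libraries from their group mean correlated with GC at up to 0.409. With the trends removed, 5 lists lost their call: ribosomal proteins went from 0.41 (interquartile range 0.415) to 0.095 (0.501), oxidative phosphorylation from 0.60 (0.222) to 0.26 (0.480), autophagy from 0.26 (0.544) to -0.04 (0.637), ZNF genes from -0.31 (1.12) to -0.26 (0.839) and DNA repair from -0.54 (0.808) to -0.25 (0.651). Relative to the median of all genes, which moved from 0.03 to -0.12, the same lists went from 0.39 to 0.22, 0.57 to 0.38, 0.23 to 0.08, -0.34 to -0.14 and -0.57 to -0.12, while the spread within the list widened for the first 3 and narrowed for ZNF and DNA repair genes, so for the first 3 the shift and the wider spread were not separated. A bias in library preparation and a real shift of short genes cannot be told apart for these lists, because the trend follows the groups and its removal takes out both.

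The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave the highest counts in 1 of 10 splits each time: 13480 changed genes, 5140 of them at least 2-fold, and 18 lists. Each of the other splits has libraries of both groups in both arms, so the difference between the groups enters the spread and these splits do not stand for unchanged samples. In them edgeR called 0 genes, with 13 to 44 genes at an unadjusted p under 0.05, and no other tool was run on them. Camera called 12 to 15 lists in them.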
